A study of Mus musculus with 6 samples.

How the data were processed

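Total RNA from the whole pancreas of newborn mice was hybridised to single-colour Agilent mouse arrays, 1 array per sample and 6 arrays in all. The labels put the samples in 3 genotypes with 2 samples each, Spink3+/+, Spink3-/- and Spink3-/-XKI/+, and all groups were taken from those labels. They do not say what XKI stands for, nor that the 2 samples of a genotype came from separate animals.

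The deposited intensity values are the processed signals of Agilent Feature Extraction 10.7.3.1, which per the file headers are background-subtracted and detrended spot signals on a linear scale, with a small surrogate value put in for spots too dim to measure. Per the file headers no step made the arrays comparable with each other, and the headers name the mouse build mm9 for the array's annotation. The value file deposited for the whole series held the same intensity for every spot, on the same linear scale, uncentred and with no ratio taken; its column medians ran from 15.2 to 19.9. Since its values are the same, no separate fit was made from them, and the alternative named for the series values repeats the main fit. The flags for spots well above background, saturated spots and outlier spots come from the same deposited scanner files, where they are 0 or 1 per spot. Gene coordinates were used for the neighbours of Spink3 alone, by order on the chromosome.

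Each array held 62976 spots, of which 59305 were not controls and carried 55681 different probes. Between 42.4% and 50.8% of those spots were well above background, no spot was saturated, and spots marked as outliers were left out. The 75th percentile of the signal lay between 111 and 155. The 6 arrays shared 1 slide and 1 scan date, so neither could be used as a block, but they lay in 2 rows of that slide.

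From these values the log2 of the processed signal was taken and each array's 75th percentile over spots that are not controls was subtracted, so a level of 0 is that percentile. Spots of the same probe were averaged. A probe was kept where it was well above background on both arrays of at least 1 genotype, which left 24820 probes, or 44.6%. Probes were named through a RefSeq table of 49997 mouse genes: 26762 by accession, 3819 by symbol and 639 by an older symbol, while 2044 kept the name in the file and 22417 had no gene name. RefSeq lists Spink3 under another symbol, and the name in the labels was kept here. A gene with several probes was represented by its brightest unsaturated probe. This gave 14167 tested genes.

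Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) on all 6 arrays, so that the 3 genotypes share 1 estimate of the spread with 3 residual degrees of freedom. Data were read with version 1.17.8 of the R package data.table, and the figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene or list was called where its adjusted p was under 0.05. The groups, the test, the named genes, the gene lists and most alternatives were fixed before the data were examined. Where a probe was not well above background on every array of the dimmer group, the fold is a lower bound, written as at least N-fold. It sets the mean of the brighter group against the higher of the dim probe's own value and the lowest signal among probes well above background, taken per array. The bound holds for the processed signal alone, and the fitted log2 difference beside it is no bound. Where the dim probe's own value is the higher on every array, the bound equals the fitted difference and is no firmer than it.

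The named genes are, per comparison, up to 10 called genes with the largest rise and 10 with the largest fall among plain symbols, with the higher group above background and no overlap between the groups; Spink3; and for each list its called members with the largest change, or up to 2 members given as values where none was called. Members past the threshold adjusted over the list alone are named in part, and other genes named outside the rule were chosen after their values were seen.

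There were 32 gene lists. Those for processes were autophagy machinery, lysosome, the unfolded protein and endoplasmic reticulum stress response, apoptosis, necroptosis with pyroptosis and the inflammasome, p53 targets, oxidative stress, acute-phase and REG proteins, cytokines with chemokines and NF-kappaB targets, interferon response, immediate early genes, cell cycle, hypoxia and glycolysis, and cholesterol biosynthesis. Those for cell types and neighbouring tissues were digestive enzymes, acinar factors, duct, endocrine, macrophages, neutrophils, lymphocytes, mast cells, fibroblasts and stellate cells, endothelial cells, erythroid cells, adipocytes, mesothelium, nerve and glia, intestine, liver and striated muscle. The last was a list of sex-linked genes. Some genes are on several lists, such as Atf3 (unfolded protein response and immediate early genes) and Lcn2 (acute-phase proteins and neutrophils). Shifts of such lists are not separate results. A list with at least 5 tested members was set against all other tested genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists tested. Camera with an estimated correlation and limma's fry were alternatives. The PValue of fry asks whether a list's genes move, on balance, one way, and its PValue.Mixed whether they change in either direction; neither compares a list with other genes.

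The method was tested on simulated data made from the spread of these arrays for Spink3-/- against Spink3+/+. In 10 draws, 200 of 14167 genes were changed. Of genes changed 2-fold, 7% were called, of those changed 4-fold 78.8%, 8-fold 94.8% and 16-fold 96.4%. Of 1457 calls, 72 were unchanged genes. With 200 changed genes the Benjamini-Hochberg threshold is easier to pass than with the 5 calls of the real comparison. The shares are therefore likely too high for it, where Egr2 at a fitted log2 of 3.33 did not pass (limma adjusted p = 0.101). A list shifted by 0.5 on the log2 scale was called in 10 of 10 draws at the preset correlation and in 1 of 10 with an estimated correlation. With either version of camera, 0 of 300 tests called an unchanged list. Each gene was drawn on its own, so the simulated members of a list were not correlated. On the real arrays the estimated correlation within lists had a median of 0.17 and reached 0.62. The simulation therefore cannot show how often such correlation leads to false list calls.

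The alternatives were normexp background correction with an offset of 50 on the mean and local background signals, quantile normalization, scaling on the spike-in probes (7 of 10 were above background on every array), the percentile over probes above background everywhere, no filter or a stricter filter on dim probes, no saturated probes, the mean over a gene's probes, each probe on its own, only the 2 groups compared, a variance trend, a log2 threshold of 1, the replicate number as a block, and each array left out in turn. The slide row as a block was added after seeing the data, as was a contrast of both Spink3-/- genotypes with Spink3+/+. One gene that the rule names is not reported here. Not analysed here were exons, splice forms, and the probes without a gene name beyond their counts.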

Results

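Gene expression was measured in the whole pancreas of C57BL/6N mice at postnatal day 0.5, in 3 genotypes with 2 arrays each. Spink3 encodes a trypsin inhibitor that acinar cells secrete together with their digestive enzymes. By the series' design, acinar cells of the Spink3-/- pancreas die throughout by a route other than apoptosis that involves autophagy, while in Spink3-/-XKI/+ part of the acinar cells stay normal. Spink3+/+ served as the control. The comparisons ask which transcripts accompany this cell death and where the partly normal pancreas lies between the other genotypes.

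The 2 arrays of a genotype were hardly closer to each other than to other arrays. Across probes, the correlation between arrays ran from 0.970 to 0.984, and replicate 1 of Spink3-/- correlated more with replicate 2 of Spink3+/+ (r = 0.982) than with its own replicate (r = 0.979). The number of arrays limits the precision of every value below. Since nothing says that the samples came from separate animals, the p-values measure only the spread between these samples, which may be technical. Where leaving out an array leaves a group with 1 sample, that sample is assumed to vary like the other groups.

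Spink3, the targeted gene, had the largest difference among the called genes. Its log2 level over the array's 75th percentile was 9.84 and 10.26 on the Spink3+/+ arrays, 3.25 and 2.95 on the Spink3-/- arrays, and 2.64 and 2.34 on the Spink3-/-XKI/+ arrays. It fell by 6.95 on the log2 scale in Spink3-/- (SE 0.23, n = 2 per group, limma adjusted p = 0.00103) and fell by 7.56 in Spink3-/-XKI/+ (SE 0.23, limma adjusted p = 0.000613). The SD between the 2 arrays was 0.30, 0.22 and 0.21 in these genotypes. The probe stayed well above background in all 6 samples, and whether it lies within the deleted part of the gene is not given in the sources used here.

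In Spink3-/- against Spink3+/+, 3 genes rose and 2 fell among 14167. Rab13, a small GTPase of vesicle traffic and tight junctions, rose at least 11.3-fold (log2 4.35, SE 0.31, n = 2 per group, limma adjusted p = 0.0313). Ces2a, a carboxylesterase, rose at least 3.36-fold (log2 3.56, SE 0.24, limma adjusted p = 0.0313). Saa3, an acute-phase serum amyloid A made outside the liver, rose at least 2.31-fold (log2 2.77, SE 0.23, limma adjusted p = 0.0443). Nsun7, of a family of RNA methyltransferases, fell at least 5.93-fold (log2 -2.57, SE 0.20, limma adjusted p = 0.0441). Its bound is only the fitted difference, because the probe's own dim values were above the lowest well-measured signal. All 4 have probes below background on both arrays of their dimmer group. Second probes of Rab13 (log2 -0.79) and Nsun7 (log2 -0.77) did not pass. That of Rab13 opposes the rise and was the brighter in Spink3+/+ (mean -1.59 against -3.41), so the bound for Rab13 holds for its first probe alone. The next gene had a limma adjusted p of 0.0714, and 717 genes lay under an unadjusted p of 0.05 where 708 would by chance.

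Calls other than Spink3 depended on single choices in this comparison. Over 12 alternatives with all arrays, Ces2a and Rab13 were called in 6 each (adjusted p from 0.00320 to 0.425 and from 0.0225 to 0.492), Nsun7 in 5 (from 0.0340 to 0.884) and Saa3 in 3 (from 0.0441 to 0.887). This and later counts of alternatives include the deposited series values and saturated probes left out. Neither could differ from the main fit, so quantile normalization was the only other of these settings in which Saa3 was called. With normexp background correction the log2 differences were 2.06 for Rab13, 1.19 for Ces2a, 0.56 for Saa3 and -1.29 for Nsun7, none called and each smaller than the bound above, which holds for the processed signal alone. All 4 were lost without Spink3-/-XKI/+ replicate 1 or replicate 2, each of which left 1 call; their log2 differences did not change, since those arrays are in neither group and bear only on the shared spread. Rab13 turned to -0.93 and -0.65 without Spink3-/- replicate 1 and replicate 2, where its other probe stood for it. Without Spink3+/+ replicate 1 or 2, or Spink3-/- replicate 1 or 2, the count became 139 (132 lower), 290 (278 lower), 280 (271 higher) and 286 (275 higher), mostly genes higher in the group left with 1 array. A probe is then tested if it is above background on that array alone, and 117, 246, 220 and 241 of the calls were genes not tested with all arrays.

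**Figure D1:**
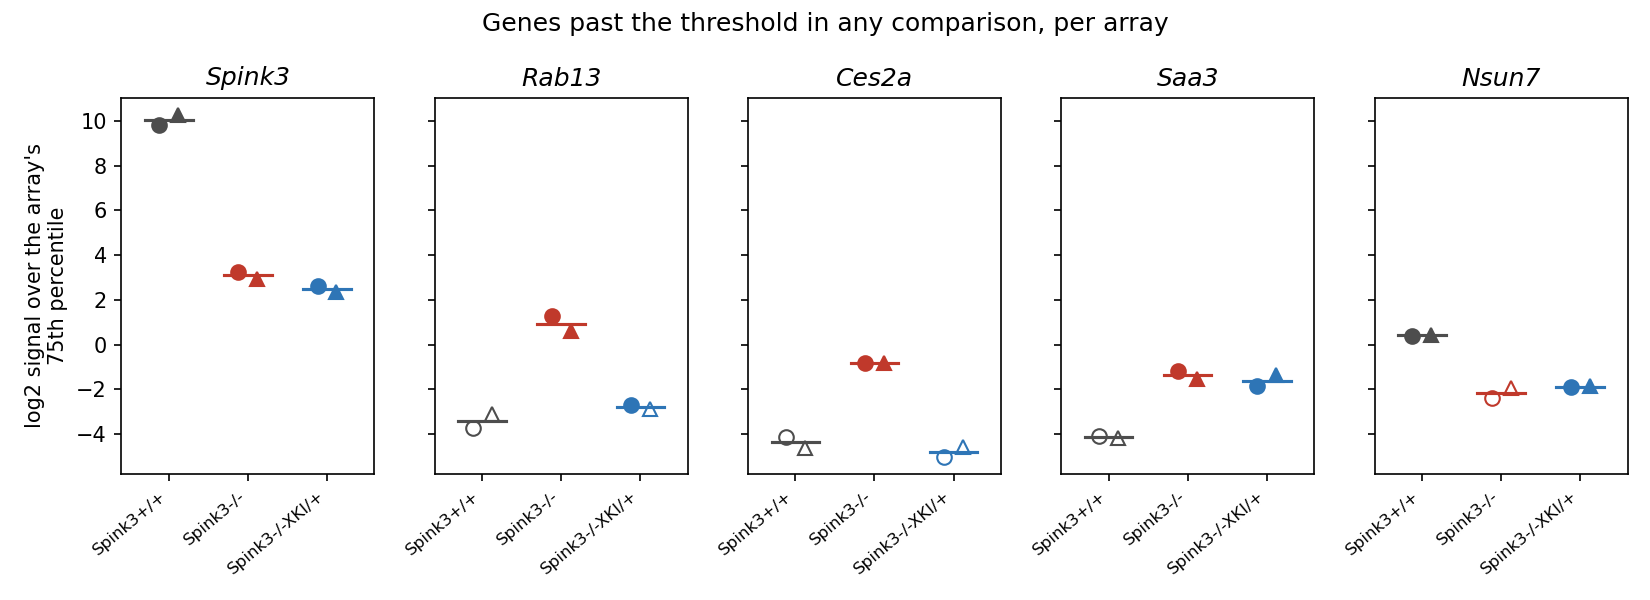
Log2 signal over the array's 75th percentile for the 5 genes called in any comparison, by genotype; circles are replicate 1, triangles replicate 2, open symbols probes not well above background, and bars the mean of 2 arrays. Spink3 lies at 9.84 and 10.26 in Spink3+/+ and at 3.25 or lower on the other arrays, while Ces2a is above background in Spink3-/- alone.

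Among the gene lists, 13 of 30 moved in Spink3-/- against Spink3+/+, 9 up and 4 down, by camera at the preset correlation. None of the list calls in any comparison holds with an estimated correlation between genes, where camera called 0 lists and the lowest adjusted p was 0.310, 0.344 and 0.417 in the 3 comparisons. Correlation alone does not account for this. Endothelial and erythroid markers, at estimated correlations of -0.006 and -0.007, below the preset 0.01, lost their calls too. That version called the simulated shifted list in 1 of 10 draws. These losses therefore neither refute nor back the list calls. By fry, which tests a list's own direction, 1, 0 and 0 lists passed, and 5, 4 and 9 changed in either direction. In other pairings of the same 6 arrays, 15 in all with the real one, camera called between 10 and 38 lists over the 3 comparisons with a median of 27, against 38 for the real one. The genes tested were those admitted by the real genotypes in every pairing.

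Liver transcripts had the highest median shift in Spink3-/-. All 14 tested members were higher than in Spink3+/+, with a median log2 difference of 1.53 (camera adjusted p = 5.7e-10; adjusted p = 0.325 with an estimated correlation). None passed over all genes. Adjusted over the list alone 4 rose: Afp, the fetal serum protein (log2 2.30, SE 0.64), Apoh (log2 2.29, at least 3.66-fold; 1 Spink3+/+ array measured it), Serpina1a, the main serum protease inhibitor (log2 2.15, SE 0.34), and Apob, the structural protein of lipoproteins (log2 2.13, at least 2.97-fold). Immediate early genes rose as a list beside it by a median of 0.73 over 15 members (camera adjusted p = 1.9e-09; adjusted p = 0.325 with an estimated correlation). Egr2, a growth-factor-induced transcription factor, was its 1 member that rose adjusted over the list alone (log2 3.33, SE 0.34, at least 2.98-fold), with 0 past the threshold over all genes.

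Acute-phase and REG proteins, macrophage markers, cytokines, necroptosis genes and interferon response genes also rose as lists in Spink3-/-, beside the liver transcripts with their median of 1.53. The acute-phase and REG proteins had a median of 0.59 over 21 members (camera adjusted p = 1.9e-09; adjusted p = 0.325 with an estimated correlation). Over all genes 1 member rose and 20 did not pass; adjusted over the list alone 4 rose, namely Saa3, the lectin Lgals3 (log2 0.94, SE 0.21), and the regenerating proteins Reg2 (log2 0.81, SE 0.20) and Reg3d (log2 0.79, SE 0.20). Macrophage markers rose by a median of 0.36 over 24 genes, 21 of them higher (camera adjusted p = 7.6e-06; adjusted p = 0.344 with an estimated correlation), with Adgre1 at 0.91 and Cd163, which marks resident macrophages, at -1.49 (at least 1.32-fold lower). The list of cytokines, chemokines and NF-kappaB targets had a median of 0.35 over 17 genes (camera adjusted p = 0.00533; adjusted p = 0.510 with an estimated correlation), and its monocyte attractants Ccl7 and Ccl2 stood at 2.29 (at least 2.6-fold; 1 Spink3+/+ array measured it) and 1.61. Necroptosis, pyroptosis and inflammasome genes had a median of 0.24 over 10 (camera adjusted p = 0.00265; adjusted p = 0.325 with an estimated correlation), with the kinase Ripk1 at 2.01 and the inflammatory caspase Casp4 at 0.65. Interferon response genes had a median of 0.21 over 23 (camera adjusted p = 0.00101; adjusted p = 0.714 with an estimated correlation), with the antiviral Mx1 at 1.74 (at least 1.56-fold; 1 Spink3+/+ array measured it) and Ifit3 at 0.95. No member of these last 4 lists passed, over all genes or adjusted over the list alone.

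Hypoxia genes and the unfolded protein response rose as lists too. Hypoxia and glycolysis genes had a median of 0.34 over 19 (camera adjusted p = 0.000552; adjusted p = 0.325 with an estimated correlation), with the glucose transporter Slc2a1 at 0.65 and Ankrd37 at -0.87 (at least 1.19-fold lower; 1 Spink3-/- array measured it). The unfolded protein and endoplasmic reticulum stress response had a median of 0.16 over 29 (camera adjusted p = 0.00312; adjusted p = 0.325 with an estimated correlation), led by the stress-induced factors Atf3 at 1.82 (at least 2.87-fold; 1 Spink3+/+ array measured it) and Trib3 at 0.85. Atf3 is on the list of immediate early genes as well. No member of the hypoxia or unfolded protein list passed, over all genes or adjusted over the list alone.

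Neutrophil, erythroid and endothelial markers and digestive enzymes fell as lists in the same comparison. Neutrophil markers had a median of -0.73 over 16 (camera adjusted p = 5.1e-05; adjusted p = 0.510 with an estimated correlation), with the granule proteins Ctsg at -1.40 (at least 2.64-fold lower; 1 Spink3-/- array measured it) and Mpo at -1.07. Erythroid genes had a median of -0.58 over 13 (camera adjusted p = 0.000112; adjusted p = 0.310 with an estimated correlation), with the haemoglobin chaperone Ahsp at -1.26. Endothelial markers had a median of -0.34, with 14 of 16 lower (camera adjusted p = 0.000116; adjusted p = 0.310 with an estimated correlation). They were the list that passed fry (adjusted p = 0.0355), with the endothelial cadherin Cdh5 at -0.57 and Sox18 at -1.11 (at least 1.04-fold lower; 1 Spink3-/- array measured it). Digestive enzymes had a median of -0.14, with 20 of 27 lower (camera adjusted p = 0.0102; adjusted p = 0.714 with an estimated correlation), with the lipase Pnlip at -1.41 and Ctrl at -0.84. No member of these 4 lists passed, over all genes or adjusted over the list alone.

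Of these 13 lists, liver, acute-phase and REG proteins, immediate early genes, erythroid and endothelial markers kept their call with any array left out. Without Spink3-/- replicate 1 the calls ended for macrophages (median 0.28), cytokines (0.29), necroptosis (0.27), interferon response (0.05), hypoxia (0.38), the unfolded protein response (0.18), neutrophils (-0.54) and digestive enzymes (0.01), which left 5 calls. Those for hypoxia and cytokines also ended without Spink3+/+ replicate 1 (0.17 and 0.23), those for neutrophils and digestive enzymes without Spink3+/+ replicate 2 (-0.20 and -0.02). Without Spink3-/- replicate 2, hypoxia and the unfolded protein response lost theirs (0.22 and 0.16). Medians moved over 1.5 times while the call stood without Spink3-/- replicate 1 for acute-phase and REG proteins (0.36), without Spink3+/+ replicate 1 for interferon response (0.11), the unfolded protein response (0.09) and digestive enzymes (-0.23), without Spink3+/+ replicate 2 for interferon response (0.38), and without Spink3-/- replicate 2 for interferon response (0.42) and digestive enzymes (-0.27). Normexp gave 0.77 for liver, 0.48 for immediate early genes and 0.15 for necroptosis, and no filter on dim probes 0.17 for cytokines. Spike-in scaling gave -0.22 for endothelial markers, 0.27 for the unfolded protein response, 0.32 for interferon response and -0.03 for digestive enzymes. The slide row as a block gave 0.42 for interferon response, 0.22 for hypoxia and -0.27 for digestive enzymes, all still called. With that block the difference rests on Spink3-/- replicate 1, the only array of its genotype in the row of the Spink3+/+ arrays. Apart from the genes tested, its medians repeat those without Spink3-/- replicate 2 and are no separate check.

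The lists for autophagy, lysosome, apoptosis and acinar factors did not pass in Spink3-/-. Autophagy genes had a median of -0.04 over 36 (camera adjusted p = 0.683), with the autophagosome genes Atg9a at -0.56 and Atg14 at -0.50. Lysosomal genes had a median of 0.06 over 35 (camera adjusted p = 0.830), with the cholesterol exporter Npc1 at -0.46 and the proton pump subunit Atp6v1h at 0.44. Apoptosis genes had a median of -0.04 over 19 (adjusted p = 0.820), with the death receptor Fas at 0.76 and Bmf at -0.49. Acinar transcription factors and secretory cell genes had a median of -0.04 over 18 (adjusted p = 0.920), where the test pointed up. No member of these lists passed, over all genes or adjusted over the list alone.

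The other lists did not pass against Spink3+/+. Their medians were 0.40 for striated muscle (adjusted p = 0.141), 0.08 for oxidative stress (0.302), where the metallothioneins Mt2 and Mt1 stood at 1.73 and 1.57, 0.07 for cell cycle (0.412), -0.06 for adipocytes (0.412) and 0.06 for cholesterol biosynthesis (0.440). They were 0.03 for p53 targets (0.442), 0.11 for mesothelium (0.475), -0.03 for mast cells (0.492), 0.06 for nerve and glia (0.532), 0.02 for endocrine cells (0.570) and 0.03 for duct cells (0.668), where Car2 stood at -1.17 and Krt8 at 0.94. Lymphocytes (median -0.07, adjusted p = 0.932) and fibroblasts (-0.01, 0.932) had a mean and a test pointing up. The 3 tested intestinal genes had a median of 0.35 and were not tested as a list.

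In Spink3-/-XKI/+ against Spink3+/+, Spink3 was the gene that fell and no gene rose. By limma, 1 gene was lower and 0 were higher, with 1072 genes under an unadjusted p of 0.05, 712 of them higher. The next genes by p did not pass: Nsun7 at -2.30, Saa3 at 2.52 (at least 1.93-fold), 3021401N23Rik at 3.03 (at least 2.39-fold), the regenerating protein Reg2 at 2.11 and the osteocalcin Bglap2 at -2.14 (limma adjusted p = 0.0856 for each). Ces2a (limma adjusted p = 0.740) and Rab13 (limma adjusted p = 0.712) did not pass, and the probe representing each was not above background on every array of either group. The second probe of Rab13 was above it on both Spink3-/-XKI/+ arrays and stood at -0.45. That of Nsun7 was also above background on both and stood at 0.58 (SE 0.94), opposite in sign to the -2.30 of its first probe. Without Spink3+/+ replicate 1 or 2 or Spink3-/-XKI/+ replicate 1, the count of 1 became 171 (161 lower), 306 (282 lower) and 226 (216 higher), of which 145, 245 and 176 were genes not tested with all arrays.

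Cholesterol biosynthesis genes fell together in Spink3-/-XKI/+. All 17 tested members were lower than in Spink3+/+, by a median of -0.68 (camera adjusted p = 2.2e-13; adjusted p = 0.375 with an estimated correlation). None passed over all genes and 4 fell adjusted over the list alone: Fdps, which makes farnesyl pyrophosphate (log2 -1.31, SE 0.24), the sterol sensor Insig1 (log2 -1.27, SE 0.20), and the late enzymes Dhcr7 (log2 -1.07, SE 0.30) and Sc5d (log2 -0.68, SE 0.17). Cell cycle genes fell as a list by a median of -0.35, with 19 of 24 lower (camera adjusted p = 2.9e-06; adjusted p = 0.375 with an estimated correlation) and the cyclin Ccnb2 at -0.77. Interferon response genes had a median of -0.37 with 20 of 23 lower (camera adjusted p = 6.7e-05; adjusted p = 0.587 with an estimated correlation) and Rsad2 at -0.90. No member of these last 2 lists passed, over all genes or adjusted over the list alone.

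Acute-phase, macrophage, cytokine and immediate early lists rose in Spink3-/-XKI/+, whereas neutrophil markers fell (median -0.40) and necroptosis genes did not pass (0.35). Acute-phase and REG proteins had a median of 0.46 with 19 of 21 higher (camera adjusted p = 3.6e-08; adjusted p = 0.375 with an estimated correlation), and 8 members rose adjusted over the list alone against 0 over all genes. These were the pancreatic stress proteins Reg3a (log2 3.18, at least 6.94-fold; 1 Spink3+/+ array measured it), Reg3b (log2 2.80, SE 0.46), Reg3g (log2 2.32, SE 0.52), Reg2 and Reg3d, together with Saa3, Lgals3 and the metalloproteinase inhibitor Timp1 (log2 1.36, SE 0.35). Macrophage markers rose by a median of 0.64 with 22 of 24 higher (camera adjusted p = 1.1e-08; adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone 4 rose, the lysozyme Lyz2 (log2 1.12, SE 0.25), Cd68 (log2 1.11, SE 0.25), the scavenger receptor Msr1 (log2 1.07, at least 2.10-fold) and Aif1 (log2 0.93, SE 0.21); over all genes 0. Cytokines, chemokines and NF-kappaB targets had a median of 0.68 with 16 of 17 higher (camera adjusted p = 2.9e-06; adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone, 3 of them rose, the chemokines Ccl6 (log2 1.10, SE 0.23) and Ccl9 (log2 0.91, SE 0.22) and Nfkb2 (log2 0.83, SE 0.18), and over all genes 0. Immediate early genes had a median of 0.44 over 15 (camera adjusted p = 0.00108; adjusted p = 0.464 with an estimated correlation), with Egr2 risen adjusted over the list alone (log2 2.17, at least 1.34-fold).

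Erythroid genes fell in Spink3-/-XKI/+ by a median of -0.97 over 13 (camera adjusted p = 1.1e-06; adjusted p = 0.344 with an estimated correlation). Adjusted over the list alone 4 of them fell, among them the band 3 anion exchanger Slc4a1 (log2 -1.50, SE 0.37), the carbonic anhydrase Car1 (log2 -1.05, SE 0.24) and Tspo2 (log2 -0.88, SE 0.18), and over all genes 0. Neutrophil markers had a median of -0.40 over 16 (camera adjusted p = 0.000266; adjusted p = 0.564 with an estimated correlation), with the antimicrobial Camp fallen adjusted over the list alone (log2 -1.11, SE 0.23). Endothelial markers had a median of -0.16 with 15 of 16 lower (camera adjusted p = 0.00470; adjusted p = 0.375 with an estimated correlation) and acinar factors a median of -0.11 over 18 (camera adjusted p = 0.0174; adjusted p = 0.587 with an estimated correlation), with 0 members past the threshold in either. Striated muscle genes, which mark a neighbouring tissue, rose by a median of 1.18 over 6 (camera adjusted p = 0.000822; adjusted p = 0.464 with an estimated correlation), or 0.59 with members below background at their bound. Its 2 arrays stood apart, at 0.50 and 1.78 over the Spink3+/+ mean. The neonatal myosin Myh8 was the 1 that rose adjusted over the list alone (log2 2.29, at least 2.53-fold).

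Of these 12 lists, cholesterol biosynthesis, macrophages, acute-phase and REG proteins, erythroid cells, cytokines kept their call in every alternative fit at the preset correlation and with any array left out. Striated muscle did so as well except under the stricter filter on dim probes, which left too few members to test. With the slide row as a block, which was added after seeing the data, the interferon median turned to 0.02 and the calls for interferon, cell cycle (-0.17) and endothelial markers (-0.15) ended. That block shifts each gene's difference by that between the 2 arrays of Spink3-/-, the only genotype in both rows. No filter on dim probes ended those for endothelial markers (-0.13) and acinar factors (-0.11). Calls also ended without Spink3+/+ replicate 1 for immediate early genes (0.34), endothelial markers (-0.22) and acinar factors (-0.18), and without Spink3+/+ replicate 2 for interferon (-0.21), neutrophils (-0.15), endothelial markers (-0.20) and acinar factors (-0.14). They ended without Spink3-/-XKI/+ replicate 1 for neutrophils (-0.16), and without its replicate 2 for interferon (-0.11), immediate early genes (0.25) and acinar factors (-0.01). Among calls that stood, the acute-phase median was 0.19 without Spink3+/+ replicate 1, 0.72 without Spink3-/-XKI/+ replicate 1, 0.12 without its replicate 2 and 0.86 with the slide row as a block. Striated muscle was 0.57 without Spink3-/-XKI/+ replicate 2, 0.50 without Spink3-/- replicate 2, 0.34 with normexp and 0.43 with no filter, and erythroid genes -0.62 without Spink3-/-XKI/+ replicate 2. Cholesterol biosynthesis was -0.42 with normexp and -1.13 with the slide row. Without Spink3-/-XKI/+ replicate 1 interferon response was -0.70, immediate early genes 0.67 and acinar factors -0.24, and neutrophils were -0.65 without Spink3+/+ replicate 1. Normexp gave -0.23 for interferon response, 0.27 for immediate early genes and -0.18 for cell cycle, spike-in scaling -0.07 for acinar factors, and the slide row 0.93 for immediate early genes, -0.70 for neutrophils and -0.40 for acinar factors.

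The remaining lists did not pass in Spink3-/-XKI/+ against Spink3+/+. Liver transcripts had a median of 0.07 with the test pointing down (adjusted p = 0.938), but rose to 0.53 without Spink3-/-XKI/+ replicate 1, where the list was called. Digestive enzymes had a median of 0.02 (0.792), with Reg1, a secreted protein of acinar cells, risen adjusted over the list alone (log2 0.99, SE 0.17), and the median turned to -0.28 and was called with the slide row as a block. Autophagy genes had a median of 0.04 with the test pointing down (0.521), lysosome 0.05 (0.443), apoptosis 0.18 (0.317), necroptosis 0.35 (0.0619) and hypoxia -0.06 (0.194). The unfolded protein response had a median of -0.08 and a mean of 0.06 (0.339), with Atf3 at 1.93 (at least 3.09-fold; 1 Spink3+/+ array measured it) and Trib3 at 1.25. Medians were -0.17 for p53 targets (0.443), where Gtse1 rose adjusted over the list alone (at least 1.38-fold), -0.11 for oxidative stress (0.511), 0.12 for endocrine cells (0.511), 0.16 for duct cells (0.521), 0.27 for nerve and glia (0.0777), 0.27 for mesothelium (0.163) and -0.22 for mast cells (0.248). They were 0.00 for lymphocytes (0.938), where the mean was 0.16 and the test pointed down, 0.13 for fibroblasts (0.392) and 0.06 for adipocytes (0.779), where the lipase Lpl rose (log2 1.02) and Fabp4 fell (log2 -0.59) adjusted over the list alone. The 3 tested intestinal genes had a median of 0.45, and the keratin Krt20 rose adjusted over the list alone (log2 1.45, SE 0.30).

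Between the knockouts, Ces2a was the gene that differed: it was at least 5.51-fold higher in Spink3-/- than in Spink3-/-XKI/+ (log2 3.99, SE 0.24, n = 2 per group, limma adjusted p = 0.0330). By limma, 1 gene was higher and 0 were lower, with 1021 genes under an unadjusted p of 0.05, 676 of them lower. Rab13 stood at 3.71 (at least 12-fold; 1 Spink3-/-XKI/+ array measured it; adjusted p = 0.0799) and Spink3 at 0.61 (adjusted p = 0.645). Ces2a was called in 6 of 12 alternatives with all arrays (adjusted p from 0.00531 to 0.576), stood at 1.11 with normexp, and was not called without Spink3+/+ replicate 1 or 2 or Spink3-/-XKI/+ replicate 2, which left counts of 0. Without Spink3-/- replicate 1 or 2 or Spink3-/-XKI/+ replicate 1 the count was 269 (252 higher), 295 (285 higher) and 172 (165 lower), of which 210, 260 and 146 were genes not tested with all arrays.

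Cholesterol biosynthesis genes were higher in Spink3-/- than in Spink3-/-XKI/+, in 16 of 17 members and by a median of 0.75 (camera adjusted p = 1.3e-15; adjusted p = 0.417 with an estimated correlation). Adjusted over the list alone 11 of them were higher, led by Fdps (log2 1.80, SE 0.24), Idi1 (log2 1.59, SE 0.37), Insig1 (log2 1.29, SE 0.20) and Msmo1 (log2 1.24, SE 0.33), and over all genes 0. Interferon response genes had a median of 0.60 with 20 of 23 higher (camera adjusted p = 3.2e-11; adjusted p = 0.443 with an estimated correlation). Here 6 were higher adjusted over the list alone, among them Mx1 (log2 2.46, at least 3.13-fold), Ifit3 (log2 1.48, SE 0.30), Ifi44 (log2 1.43, at least 2.64-fold; 1 Spink3-/-XKI/+ array measured it) and the ubiquitin-like Isg15 (log2 1.40, SE 0.32), and over all genes 0. Liver transcripts were higher by a median of 1.53 in 14 of 14 (camera adjusted p = 7.7e-10; adjusted p = 0.417 with an estimated correlation), with 0 past the threshold over all genes and Apoh (log2 2.61, at least 6.09-fold; 1 Spink3-/-XKI/+ array measured it) and Serpina1a (log2 2.22, SE 0.34) higher adjusted over the list alone. Cell cycle genes had a median of 0.38 with 20 of 24 higher (camera adjusted p = 7.0e-08; adjusted p = 0.417 with an estimated correlation). Of these, 6 were higher adjusted over the list alone, such as the topoisomerase Top2a (log2 1.25, at least 2.37-fold; 1 Spink3-/-XKI/+ array measured it) and the mitotic cyclin Ccnb1 (log2 1.08, SE 0.20), and over all genes 0.

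Hypoxia and glycolysis genes were higher in Spink3-/- than in Spink3-/-XKI/+ by a median of 0.28 (camera adjusted p = 4.3e-06; adjusted p = 0.417 with an estimated correlation), with the hexokinase Hk2 at 1.17 and Bnip3 at 0.87. The unfolded protein response had a median of 0.21 (camera adjusted p = 0.000303; adjusted p = 0.417 with an estimated correlation), with Herpud1 at 0.64 and Ddit3 at -0.57. Immediate early genes (median 0.25, camera adjusted p = 0.00719; adjusted p = 0.530 with an estimated correlation), acinar factors (0.13, camera adjusted p = 0.0203; adjusted p = 0.575 with an estimated correlation) and erythroid genes (0.22, camera adjusted p = 0.0486; adjusted p = 0.443 with an estimated correlation) were higher, and the zinc transporter Slc39a5 of the acinar list was higher adjusted over the list alone (log2 0.98, SE 0.19). Lower lists were cytokines (-0.31, camera adjusted p = 0.0203; adjusted p = 0.530 with an estimated correlation), macrophages (-0.34, camera adjusted p = 0.0224; adjusted p = 0.575 with an estimated correlation), striated muscle (-0.67, camera adjusted p = 0.0435; adjusted p = 0.575 with an estimated correlation) and digestive enzymes (-0.12, camera adjusted p = 0.0284; adjusted p = 0.660 with an estimated correlation). Of the digestive enzymes, Pnlip (log2 -2.50, SE 0.32) and the phospholipase Pla2g1b (log2 -1.18, SE 0.18) were lower adjusted over the list alone.

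Cholesterol biosynthesis, interferon response, liver, and hypoxia and glycolysis kept their call between the knockouts in every alternative fit at the preset correlation and with any array left out. Without Spink3-/- replicate 1 the calls ended for cell cycle (0.11), the unfolded protein response (0.16), immediate early genes (0.04), acinar factors (0.28), digestive enzymes (0.01), striated muscle (-0.74) and erythroid genes (0.27). Without its replicate 2 they ended for acinar factors (0.04), cytokines (-0.09), macrophages (-0.16), erythroid genes (0.35) and striated muscle (-0.22). They ended without Spink3-/-XKI/+ replicate 1 for digestive enzymes (-0.13), immediate early genes (0.20) and macrophages (-0.17), and without its replicate 2 for acinar factors (-0.04), cytokines (-0.19), erythroid genes (0.01) and striated muscle (-0.13). The counts of lists without Spink3-/- replicate 1 and replicate 2 were 7 and 8. Among calls that stood, the liver median was 0.62 without Spink3-/-XKI/+ replicate 1, 2.37 without its replicate 2 and 0.92 with normexp. Interferon response was 0.37 without Spink3-/- replicate 1, 0.35 without Spink3-/-XKI/+ replicate 2, 0.40 with normexp and 0.36 with the slide row as a block. Without Spink3-/- replicate 2 cell cycle and immediate early genes were each 0.57 and digestive enzymes -0.27; cell cycle was 0.23 with normexp and 0.11 with the slide row. Without Spink3-/-XKI/+ replicate 1 acinar factors were 0.41, erythroid genes 0.60 and striated muscle -1.06. Digestive enzymes were -0.21 without its replicate 2 and -0.04 with spike-in scaling, and acinar factors 0.21 with spike-in scaling and 0.28 with the slide row. With the slide row as a block, immediate early genes (0.04), digestive enzymes (0.01), erythroid genes (0.23) and striated muscle (-0.74) were no longer called, and other alternatives ended further calls of acinar, cytokine, erythroid and striated muscle genes. Here that block sets Spink3-/- replicate 2 alone against Spink3-/-XKI/+, as leaving out Spink3-/- replicate 1 does, and is no separate check.

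The lists that did not pass between the knockouts included autophagy machinery, with a median of -0.08 and a test pointing up (adjusted p = 0.938), lysosome at -0.09 (0.441), apoptosis at -0.11 (0.221), necroptosis at 0.11 (0.422), oxidative stress at 0.05 (0.0835) and acute-phase and REG proteins at -0.12 (0.413), of which Reg2 was lower adjusted over the list alone (log2 -1.29, SE 0.20). P53 targets had a median of 0.20 (0.0836), with Gtse1 lower adjusted over the list alone (log2 -1.15, at least 1.28-fold). Medians were -0.06 for duct cells (0.938), -0.01 for endocrine cells (0.938), -0.11 for fibroblasts (0.363), -0.11 for endothelial cells (0.517), -0.06 for mesothelium (0.517), -0.13 for nerve and glia (0.321) and -0.34 for adipocytes (0.342), where Lpl was lower adjusted over the list alone (log2 -1.08, SE 0.19). They were -0.06 for neutrophils (0.939) and -0.05 for lymphocytes (0.938), with the test pointing up in both, and 0.04 for mast cells (0.629), whose mean was just under 0. The 3 intestinal genes had a median of 0.24 and a mean of -0.17, with Krt20 lower adjusted over the list alone (log2 -1.10, SE 0.30).

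**Figure D2:**
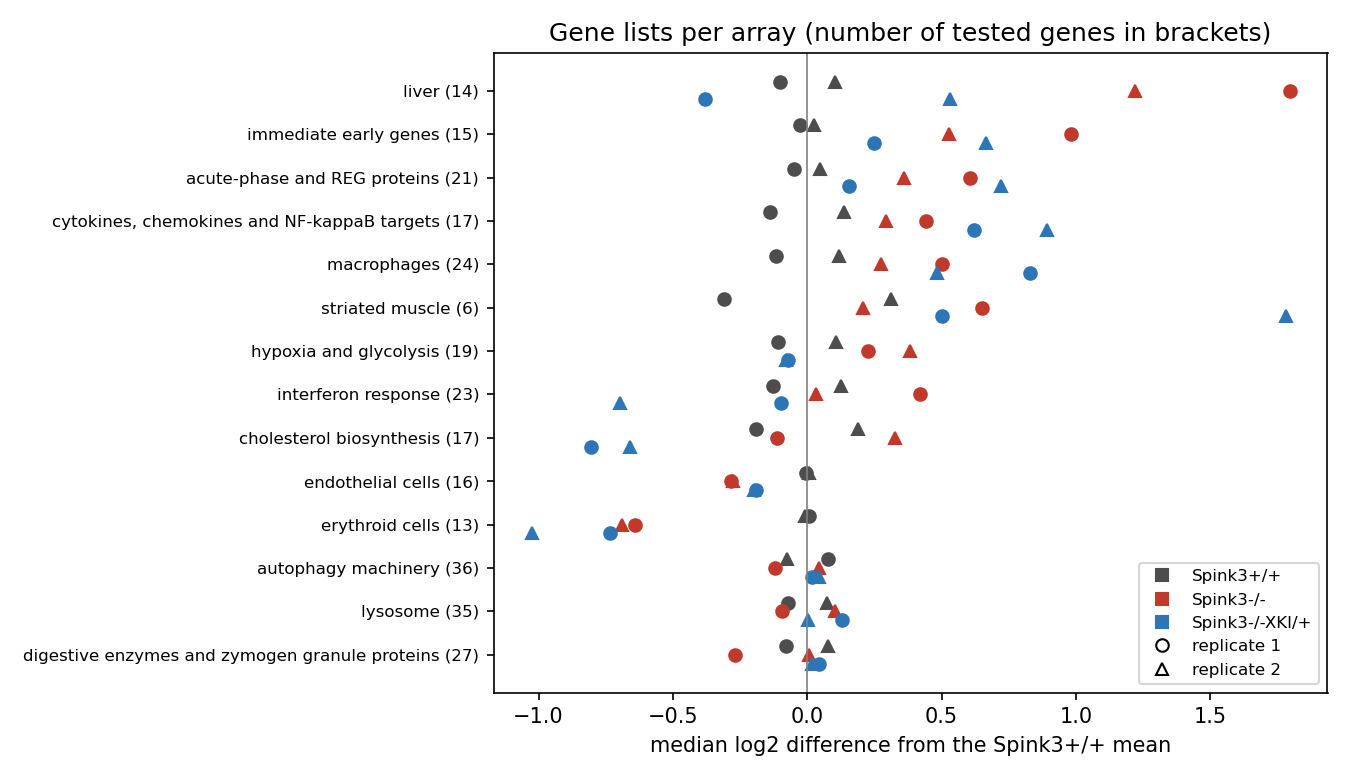
Median over a list's tested genes of the log2 difference from the Spink3+/+ mean, 1 symbol per array (circles replicate 1, triangles replicate 2), for 14 lists. Both Spink3-/-XKI/+ arrays lie lowest for cholesterol biosynthesis (-0.81 and -0.66), and both Spink3-/- arrays highest for liver (1.80 and 1.22).

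The position of Spink3-/-XKI/+ between the other genotypes was taken from few genes. For the 5 genes called in Spink3-/- against Spink3+/+, the difference of Spink3-/-XKI/+ from Spink3+/+ was divided by that of Spink3-/-, so that 0 is the level of Spink3+/+ and 1 that of Spink3-/-. The ratio was -0.12 for Ces2a, 0.147 for Rab13, 0.895 for Nsun7, 0.907 for Saa3 and 1.09 for Spink3, with a median of 0.895. The probes used for Ces2a, Rab13 and Saa3 are below background on both Spink3+/+ arrays and that for Nsun7 on both Spink3-/- arrays, so these ratios rest on levels that the probes did not measure, and Spink3 is the deleted gene in both. Second probes, not used here, stood at -0.79 in Spink3-/- and -0.45 in Spink3-/-XKI/+ for Rab13, and at -0.77 and 0.58 for Nsun7. The ratios therefore do not settle the position. The median also rests on which genes are called: it lay between 0.148 and 1.09 over the alternatives with all arrays, at -0.0459 and -0.0928 without Spink3-/- replicate 1 and replicate 2, and between 1.07 and 1.11 without any other array.

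Across genes, the log2 differences of both knockouts from Spink3+/+ correlated at r = 0.527, where unchanged groups simulated against the same control arrays gave 0.497 on average (0.434 to 0.548 in 50 draws). The covariance was 0.0869 against a simulated 0.0643 (0.0538 to 0.0809), a difference of 0.0225, and 66.3% of genes had the same sign against 66.6%. The correlation lies within the simulated range and the covariance above it. The simulation contains the shared controls but no effects, and genes are not independent replicates, so the excess is not read as a shared effect. The calls of both comparisons share 1 gene, Spink3, which is deleted in both by design.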

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

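The tests of explanations in this part were chosen only after the results were seen.

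Ces2a was flagged because Spink3-/- and Spink3-/-XKI/+ differ in it by a test of the difference itself. It was at least 5.51-fold higher in Spink3-/- (fitted log2 difference 3.99, which is no bound; limma adjusted p = 0.0330), while in Spink3-/-XKI/+ its probe stayed below background on both arrays, as in Spink3+/+.

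Gene lists were flagged where both arrays of one knockout lay above the Spink3+/+ mean and both of the other below it; this opposite movement was not tested. The interferon response (medians 0.42 and 0.03 in Spink3-/-, -0.10 and -0.70 in Spink3-/-XKI/+) differed by 0.60, hypoxia and glycolysis (0.22 and 0.38 against -0.07 and -0.08) by 0.28, and the unfolded protein and endoplasmic reticulum stress response (0.16 and 0.18 against -0.07 and -0.12) by 0.21. The Spink3+/+ arrays themselves lay at -0.13 and 0.13, at -0.11 and 0.11, and at -0.06 and 0.06 in these lists, in that order. Within that spread lie both Spink3-/-XKI/+ values for hypoxia, and the 0.03 and -0.10 for interferon. Opposite sides of the mean are thus not shown to be opposite movements. Camera at the preset correlation called the direct difference in all 3, with an estimated correlation in none.

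Probes that the files name only by an interval of the mouse build mm9, with no gene, were flagged as a signal outside the genes compared. Tested among 24818 single probes, 6 of them were called in Spink3-/- against Spink3+/+, 1 higher and 5 lower, with log2 differences from -5.05 to 3.23; in Spink3-/-XKI/+ 1 was called. No gene was assigned to them here.

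Liver transcripts were higher in Spink3-/- than in both other genotypes, by a median of 1.53 against each. If liver tissue came along with the pancreas, liver transcripts outside the list should rise too. Of 35 tested, 42.86% were above both Spink3+/+ arrays on both Spink3-/- arrays, against 16.15% of all genes (binomial p = 0.000166). That p treats the transcripts as independent and does not measure the spread between samples, while the liver list had an estimated correlation of 0.397. The set also holds Serpina1c, Serpina1d and Serpina1e, beside the list's own Serpina1a and Serpina1b. The share fell short of the majority that was set as the bound before the share was seen, under which the test would have counted against liver tissue. The reading was changed to undecided after the value was seen, because that set was not ranked by abundance in newborn liver and holds transcripts already bright in the control pancreas, such as Vtn at 3.20 and F10 at 6.43. Against liver tissue also speak Apoc3 at -0.15 and Hrg at -0.27, so the cause stays open between liver tissue, single samples and induction within the pancreas. In both Spink3+/+ samples 12 of 14 list members were above background. This decides nothing, since those samples could hold liver tissue as well. The share of pairs of arrays with a list median as far out was 0.0667, which cannot be lower with 6 arrays, so it decides nothing about single samples.

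Cholesterol biosynthesis genes were lower in Spink3-/-XKI/+ than in both other genotypes. Both of its arrays lay in the lower row of the slide, together with Spink3-/- replicate 2, but that array was higher than their mean by 1.06, against an SD of 0.24 between replicates, which speaks against place on the slide. It is 1 array, however, and the row separates all Spink3+/+ from all Spink3-/-XKI/+ arrays, so the cause stays open; this was first read as excluding the slide, and the reading was changed after the value was seen. Differences between single samples were not decided either: the share of pairs of arrays as far out was 0.0667, which cannot be lower with 6 arrays.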

How the results depend on the processing

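Spink3 kept its fall in Spink3-/- in every alternative, and in Spink3-/-XKI/+ in every one except with the slide row as a block, which was added after seeing the data (-7.25, no longer called). Of 38 list calls, 27 were kept in all 14 settings with all arrays at the preset correlation, and striated muscle in Spink3-/-XKI/+ in the 13 that left enough members; 15 of these 28 also stood with any array left out. Among those 14 settings, the series values and saturated probes left out repeat the main fit. The slide row as a block estimates the differences of Spink3-/- as with 1 of its arrays left out. Camera with an estimated correlation called 0, 0 and 0 lists and fry 1, 0 and 0, in the order Spink3-/- against Spink3+/+, Spink3-/-XKI/+ against Spink3+/+, and Spink3-/- against Spink3-/-XKI/+. In that order the genes called numbered 1, 2 and 0 with normexp, 7, 3 and 4 with quantile normalization, 6, 1 and 2 with spike-in scaling, 1, 1 and 0 with no filter on dim probes, with probes above background everywhere and with only the 2 groups compared, 2 in the first with the mean over probes, 11, 2 and 0 with each probe tested alone, 2, 2 and 0 with a variance trend, and 1, 0 and 3 with the slide row as a block. The median position of Spink3-/-XKI/+ was 1.08 with normexp, 0.162 with quantile normalization, 0.520 with the percentile over bright probes, 0.148 with spike-ins, 1.09 with no filter, with the stricter filter and with only 2 groups, 0.484 with the mean over probes, 0.617 with the trend and 1.07 with the slide row. It follows from which genes are called. With the slide row as a block, which separates all Spink3+/+ from all Spink3-/-XKI/+ samples, the median of digestive enzymes in Spink3-/-XKI/+ turned to -0.28 and that of the interferon response to 0.019. Only Spink3-/- has arrays in both rows, so the row term is the difference between its replicates 1 and 2. These stood at -0.27 and 0.01 for digestive enzymes and at 0.42 and 0.03 for interferon response. The turns follow from those arrays, and row and sample cannot be told apart in them.

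The replicate number as a block gave 1, 1 and 0 genes and a position of 1.09, ending the calls of Rab13, Saa3, Nsun7 and, in both comparisons, Ces2a. It added a list call for necroptosis in Spink3-/-XKI/+ (0.35) and changed no other list call. Other alternatives with all arrays also added calls, such as nerve and glia in Spink3-/-XKI/+ and p53 targets between the knockouts. Deviations from the genotype mean correlated between arrays of the same number at r = -0.0553, 0.0306 and 0.199. No value for unpaired samples was set beside them. The last is for the knockouts, whose replicates 2 differed by a median absolute log2 of 0.206. Within Spink3-/- and Spink3-/-XKI/+ it was 0.279 and 0.234, so pairing of the knockouts is not excluded. Slide and scan date as blocks were not run, since all arrays share 1 of each. A log2 threshold of 1 changed no count, while the series values and saturated probes left out repeat the main fit. Spike-in scaling moved the median of all genes in Spink3-/- against Spink3+/+ to 0.11; no called list turned its direction under any scaling.

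With one array left out, the genes called ran from 1 to 290, from 1 to 306 and from 0 to 295, the lists from 5 to 14, from 8 to 13 and from 7 to 13, and the position from -0.0928 to 1.11, at -0.0459 without Spink3-/- replicate 1. The genes tested also changed, to between 14573 and 15383. Most calls in the high counts, such as 246 of 290, were genes not tested with all arrays, admitted because a group left with 1 array needs signal on that array alone. Rab13 in Spink3-/- against Spink3+/+ ran from -0.93 without Spink3-/- replicate 1 to 4.65 without Spink3+/+ replicate 2, and was -0.65 without Spink3-/- replicate 2, as another probe then represents it. The liver list in Spink3-/-XKI/+ ran from -0.38 without its replicate 2 to 0.53 without its replicate 1; the cause was not tested. Between 42.4% and 50.8% of spots were well above background, so dim genes are measured as bounds.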

Other observations

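The tests in this part, the contrast of both Spink3-/- genotypes with the control and the regrouping of the arrays were chosen only after the results were seen.

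Taking both Spink3-/- genotypes together (4 arrays against 2), Saa3 rose and Nsun7 fell (limma adjusted p = 0.0418 for both) beside Spink3, which fell by 7.26 (limma adjusted p = 0.000329). No size is given for Saa3, below background on both Spink3+/+ arrays, or Nsun7, below it on both Spink3-/- arrays. The call of Nsun7 holds for its brightest probe alone, as its other probe stood at -0.77 in Spink3-/- and at 0.58 in Spink3-/-XKI/+. The next genes by p, Slc13a3, a transporter of dicarboxylates, Rab13 and Egr2, did not pass (adjusted p = 0.177 for each). Acute-phase and REG proteins had a median of 0.47 (camera adjusted p = 3.0e-10), macrophages 0.46 (camera adjusted p = 3.7e-09), immediate early genes 0.58 (camera adjusted p = 3.6e-07), cytokines 0.47 (camera adjusted p = 1.2e-05) and necroptosis genes 0.31 (camera adjusted p = 0.00326). With an estimated correlation none of these 5 passed (adjusted p = 0.318 for each). The lists of neighbouring tissues rose too, liver by 0.67 (camera adjusted p = 0.000149; 0.487 with an estimated correlation) and striated muscle by 0.65 (camera adjusted p = 0.00326; 0.492 with an estimated correlation). The liver rise came from Spink3-/- (1.53, against 0.07 in Spink3-/-XKI/+). Erythroid genes fell by 0.77 (camera adjusted p = 8.2e-07; adjusted p = 0.299 with an estimated correlation). Neutrophil markers fell by 0.57 (camera adjusted p = 1.1e-05), cholesterol biosynthesis genes by 0.28 (camera adjusted p = 6.9e-06), endothelial markers by 0.24 (camera adjusted p = 8.4e-05) and cell cycle genes by 0.14 (camera adjusted p = 0.0153). With an estimated correlation these 4 had adjusted p = 0.487, 0.487, 0.299 and 0.641, and no list passed. The falls of cholesterol biosynthesis (-0.68) and cell cycle genes (-0.35) came from Spink3-/-XKI/+, against 0.06 and 0.07 in Spink3-/-.

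Liver transcripts outside the list that were bright in Spink3-/- included Serpina1c, which went from 2.10 and 2.19 in Spink3+/+ to 4.27 and 4.33, and Kng1, from 0.03 and 0.56 to 2.61 and 2.70. The gains of the list's Afp were unequal between the Spink3-/- arrays, from 0.32 and 0.64 to 3.33 and 2.24, as were those of Alb, from -0.23 and 0.35 to 2.13 and 1.44. Erythroid genes, which a newborn liver also carries, fell by 0.58 in the same comparison.

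If the deleted allele carried a flanking segment of another strain, genes beside Spink3 might differ more often than others. Of 45 tested neighbours, taken from 100 genes on each side, 4 (8.89%) lay under an unadjusted p of 0.05 in the pooled contrast, against 6.04% of all genes (Fisher's exact p = 0.348; odds ratio 1.52, 95% interval 0.394 to 4.21), which leaves the question open. They were Jakmip2 at 1.71, Gm3734 at 0.67, Spry4 at -1.31 and Stk32a at 0.45.

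Xist was above background in all 6 samples, at 2.05 to 2.54, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty in none. The first 3 principal components held 31.6%, 23.5% and 20.2% of the variance. Summed over the 3 comparisons, the pairing of the labels gave 7 gene calls, for 5 different genes, where the other pairings gave at most 3 calls. All pairings used the genes admitted by the real genotypes, so genes above background only on a mixed pair of arrays were not tested. That favours the labels in advance, and the deleted Spink3 was called in both comparisons with Spink3+/+. The counts are therefore not evidence for the labels.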
